A study of Mus musculus with 5 samples.

How the data were processed

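RNA was extracted from hearts, poly-A RNA was selected and libraries were made with a NEBNext Ultra kit, per the labels' protocols. The labels do not say whether the libraries keep strand, so reads of overlapping and antisense genes cannot be told apart. Reads were placed on mm10, per the submitters' processing notes. The aligner, the counting tool and the annotation are not given in the sources used here. The authors deposited 1 table of log2 values for 17818 gene symbols in 5 columns, and 0 columns were left without a sample. Column names were tied to samples through the labels.

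What the deposited log2 values hold was worked out from the values. In each library they follow log2 of the count plus 0.5, scaled to the library total as CPM, which is the form limma's voom gives. In the 4 Tet2 columns the deposited log2 value is 0.75 of the library's own value plus 0.25 of that of the other replicate. With that weight undone, 99.92% to 99.94% of genes per column gave a whole count within 0.01, against 9.06% to 10.4% as deposited and at most 10.1% at the other weights tried between 0.6 and 0.9. The WT column was fitted in the same way by a pair of whole counts at weight 0.75 for 99.88% of 6586 genes, against 24.0% to 25.9% at the other weights tried. The second count of that pair is not a column of the table. Its ratio to the first had a standard deviation of 0.0575, where a uniform spread of 10% either side of 1 has 0.0577, and both counts were equal in 99.92% of 2422 genes with 1 to 4 counts. The WT column was used as deposited and counted as 1 sample. How the mixes arose is not given in the sources used here.

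The total was 15002794 counts for WT vector, whose mix was not undone. The recovered totals were 15535778 and 15334618 for Tet2 vector and 14626806 and 14574823 for Tet2 oridonin. A floor of 3 counts corresponds to 0.193 to 0.206 CPM. Genes of the mitochondrial genome took 23.6% of counts in WT, 26.8% and 29.7% in Tet2 vector and 30.2% and 28.2% in oridonin libraries (95% Wilson intervals at most 0.024 percentage points to either side, which cover counting error only).

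The plan made before the data were examined assumed raw counts or a plain normalized unit, with a count test or limma on log2 of the value plus 1. The table held neither. Limma's trend method with robust empirical Bayes was therefore fitted to the unmixed log2 values, with group as the only term and all 5 libraries in 1 fit. Genes with at least 1 CPM in at least 2 libraries were kept, which left 12734. The fit has 2 residual degrees of freedom, all from the Tet2 groups, and the lone WT library is assumed to vary like them. P-values were adjusted by Benjamini-Hochberg within each comparison at an FDR of 0.05. Both the use of unmixed values and the fit to deposited values beside it were chosen after the data were seen. Undoing the mix leaves the fold changes of the Tet2 groups as they are and returns the replicate spread to the size the counts give.

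Gene lists were fixed before the data were examined. There were 37, for themes of the study, heart muscle, matrix, metabolism, stress responses, cell types that a heart piece can hold, and checks of dissection and time of day. The 31 with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over lists. Camera with an estimated correlation and fry were alternatives. With an estimated correlation 0 of the calls held in any comparison, and with fry 1 held in Tet2 vector against WT, 0 in oridonin against vector and 1 in oridonin against WT, all of them the glucocorticoid list. Unlike the preset, camera with an estimated correlation is judged on the 2 residual degrees of freedom. A call lost there cannot be put down to correlation among members alone. Both may play a part where the estimated correlation was far above the preset, as in red cell genes (0.875) and nuclear respiratory chain genes (0.723). The preset p-values of such lists assume less correlation than was estimated. In oridonin against vector the fibroblast list had an estimated correlation of -0.031, below the preset. Its adjusted p in camera still went from 1.07e-19 to 0.172. For single members, the adjusted p over the list alone stands beside that over all genes.

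Named genes followed a rule fixed beforehand. Tet2 and Kdm5c were always named. Where fewer than 5 genes passed in a direction, the 5 with the smallest unadjusted p were taken, among genes with a mean of at least 1 CPM, groups that do not overlap and a symbol that is not a predicted or pseudogene name. From each list described, up to 4 members with the smallest unadjusted p were taken. Outside the rule and after their values were seen, Cdkn2a, Il6, Il1a, Myl7, Sln, Bmp10, Thbs2, Nppb, Car3, Cfd, Plin1, Cidec, Adipoq, Lipe, Cidea, Adig, single members past the threshold adjusted over the list alone and the neighbouring genes of the closing part were named. Some genes named for 1 comparison were also given in others, and values are not given for every gene that the rule picked.

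Positions come from GENCODE release M21 on GRCm38, the assembly that mm10 names, and 17042 of 17818 symbols matched 1 gene there. The scan for neighbouring genes was first run with circular shifts along the genome, which gave a permutation p of 0.501 for oridonin against vector. Such shifts carry a cluster along intact and so do not test clustering, and a permutation of the genes, chosen after that value was seen, replaced them (permutation p = 0.003, and 0.673 and 0.164 in the comparisons with WT). Alternatives to the main analysis were limma without trend, other scalings, filters, pseudocounts and thresholds, a replicate block and each library left out. After the data were seen, the deposited values, voom on recovered counts, size factors from median ratios for the gene counts, a pseudocount of 1 CPM, a crossed pairing of the replicates and simulated lists cut to the observed lengths were added. For the lists, median ratios were planned, and quantile normalization, median centring and library size without mitochondrial genes were added. The crossed split of the 4 Tet2 libraries, fitted to those 4 alone, was also chosen then. Count-based tests other than voom were not run on the recovered counts. Each simulated gene was drawn independently of the others. Variances in the simulations were drawn from the prior that limma fitted. They replaced the moderated variances of the first version after its values were seen. The steps were tested on simulated counts for the 12734 genes. Recovery of changes in genes at low levels was not tested. Among genes with a mean CPM well above the minimum of the filter, 100 were changed 2-fold and 100 changed 8-fold. Without the mix, 3% and 78% of them were recovered in Tet2 vector against WT and 11% and 93% in oridonin against vector, with 1 and 4 unchanged genes called. With the mix, 808 and 778 unchanged genes were called. Tools were R 4.3.3, limma 3.58.1, statmod 1.5.0, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.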

Results

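Messenger RNA was sequenced from hearts of male mice that had received a bone marrow transplant, as a model of clonal hematopoiesis, the expansion of blood cells that carry a mutation such as loss of 1 copy of Tet2. Tet2 encodes an enzyme that oxidises methylated cytosine in DNA. The labels give 3 groups. They were 1 library from a wild-type (WT) control given vector, 2 libraries from transplanted animals labelled Tet2+/- given vector and 2 from such animals given oridonin, a diterpenoid from the herb Rabdosia rubescens. The hearts were taken 12 months after transplantation, and treatment lasted 2 months. The sample titles give 1 month or 2 months where the other labels give 2 months for every sample, and the title number served here only as a replicate number. The series title names KDM5C, a demethylase of histone H3, as the target of oridonin, and the senescence-associated secretory phenotype as the process studied.

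The table held 17818 gene symbols for 5 libraries. Each Tet2 column carried 3/4 of its own log2 value and 1/4 of that of the other replicate of its group, so that replicate differences were 0.5 times their original size and group means were as they would be without the mix. After the mix was undone, whole counts (within 0.01) returned for 99.92% to 99.94% of genes in the Tet2 columns. The recovered totals were 15535778 and 15334618 counts in the Tet2 vector libraries and 14626806 and 14574823 in the oridonin libraries. The WT column held 15002794 counts and was likewise a mix, of counts and a second set of counts that lay between 0.885 and 1.115 times the first. That pair differed by less than the sampling noise, with a chi-square per gene of 0.228 at 100 to 199 counts, where counting noise alone gives 1. It was counted as 1 sample. The chi-square per gene was 44.2 between the Tet2 vector replicates and 21.4 between the oridonin replicates. Levels below are CPM, counts scaled to the library total. They come from the unmixed values in the Tet2 libraries and from the mix as deposited in the WT library, and the WT group has no replicates. Nothing in the labels says how the replicates were drawn beyond their being separate samples, so the p-values measure only the spread between these samples.

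Tet2 itself (chromosome 3, 133463679 to 133545139, GRCm38, minus strand) was at 15.6 CPM in the WT heart, 19.2 and 7.76 CPM in the Tet2 vector hearts and 9.43 and 17.9 CPM in the oridonin hearts. The log2 fold change of Tet2 vector over WT was -0.35 with a standard error of 0.62 (limma, adjusted p = 0.88). A heart library reads mostly heart cells, so this level does not check the genotype of the transplanted marrow. Kdm5c (chromosome X, 152233020 to 152274535) was at 46.4 CPM in the WT heart, 37.7 and 22.1 CPM in the Tet2 vector hearts and 27.5 and 31.6 CPM in the oridonin hearts (limma, adjusted p = 0.591 for Tet2 vector against WT and 1 for oridonin against vector). The labelled sex matched the libraries: Ddx3y and other Y-linked genes were expressed in all 5, with Ddx3y between 26.5 and 81.6 CPM, and Xist had at most 4 counts.

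The first comparison asked how the hearts of animals labelled Tet2+/- (Tet2 hearts below) differed from the WT heart under vector. Genes of the extracellular matrix, the scaffold that fibroblasts lay down in fibrosis, rose together in the Tet2 vector hearts, with a median log2 fold change of 0.65 over 44 tested members, 37 of them higher. Fmod, a small collagen-binding proteoglycan, was at 12.6 and 11 CPM against 0.516 CPM in WT. Col3a1, a fibrillar collagen, was at 180 and 163 CPM against 50.4 CPM, and Col1a1 at 99.3 and 102 CPM against 38.3 CPM. Postn, a matrix protein of activated fibroblasts, was at 87.0 and 141 CPM against 35.8 CPM. Within this list, 0 members passed the false discovery rate (FDR) of 0.05 over all genes tested and 15 passed when adjusted over the list alone, 14 higher and 1 lower. The lower one was Thbs2, with a log2 fold change of -0.90. The list test (camera, preset correlation) gave an adjusted p = 2.5e-10, and the call was lost with an adjusted p = 0.503 with an estimated correlation. Here and below, the test with an estimated correlation has only 2 residual degrees of freedom, so it has little power for any list.

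Interferon-stimulated genes rose by a median log2 of 0.76 over 34 members, 31 of them higher (camera, adjusted p = 2.97e-10, and adjusted p = 0.503 with an estimated correlation). Igtp, a GTPase of the interferon-gamma response, was at 45.8 and 55.2 CPM against 15.3 CPM, and the guanylate-binding protein gene Gbp2 at 43.1 and 52.2 CPM against 19.4 CPM. In this list 0 members passed over all genes and 3 passed when adjusted over the list alone, Igtp, Gbp2 and Gbp3. Macrophage and monocyte markers rose by a median log2 of 0.69 over 25 members (camera, adjusted p = 1.02e-05, and adjusted p = 0.503 with an estimated correlation). Their median log2 over WT was 0.91 in Tet2 vector replicate 1 and 0.44 in replicate 2. Among these markers were Aif1 at 2.70 and 3.13 CPM against 0.583 CPM and Ccr2, the receptor that draws monocytes into tissue, at 4.25 and 4.50 CPM against 1.53 CPM, with 0 members past the threshold over all genes and 0 adjusted over the list alone.

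Of 49 listed genes of the senescence-associated secretory phenotype, 29 were tested and the rest were absent or below the filter. Those tested rose by a median log2 of 0.33, 22 of them higher (camera, adjusted p = 0.00161, and adjusted p = 0.503 with an estimated correlation). None passed singly, with 0 over all genes and 0 adjusted over the list alone, against 5 at an unadjusted p under 0.05 in limma, and 9 of them were called on the deposited mixed values. The chemokine gene Ccl8 was at 17.8 and 6 CPM against 1.65 CPM, and Igfbp3 at 42.6 and 49.2 CPM against 23.9 CPM. Ccl7 had 0 counts in the WT library and 42 and 8 counts in the Tet2 vector libraries. Il6 had at most 2 counts and Il1a at most 2 counts in any library, which is under the floor of 3 counts. Cell cycle inhibitors and p53 targets did not move as a list (median log2 0.00 over 22 members; camera, adjusted p = 0.764). Cdkn1a, the cell cycle inhibitor p21, was lower in the Tet2 vector hearts at 14.7 and 16.9 CPM against 40.9 CPM (log2 fold change -1.37, standard error 0.28; limma, adjusted p = 0.324), and Cdkn2a had 28 and 1 counts against 2.

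Heart muscle genes moved in both directions in this comparison. Actc1, the cardiac alpha-actin, was at 14200 and 13100 CPM against 5210 CPM in WT, and Myom2, a protein of the sarcomere M band, at 615 and 663 CPM against 1620 CPM. These 2 were the members of the cardiomyocyte list past the threshold adjusted over the list alone, against 0 over all genes, and the list of 29 did not move (camera, adjusted p = 0.827). Genes of fatty acid uptake and oxidation, the main fuel route of the adult heart, fell by a median log2 of 0.24 over 40 members (camera, adjusted p = 0.000825, and adjusted p = 0.503 with an estimated correlation). The fatty acid transporter gene Cd36 was at 1460 and 1450 CPM against 2280 CPM. No member of that list passed, with 0 over all genes and 0 adjusted over the list alone.

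Over the whole transcriptome, limma called 0 of 12734 genes between Tet2 vector and WT at an FDR of 0.05, with a smallest adjusted p of 0.208. At an unadjusted p under 0.05 there were 1221 genes, 644 higher and 577 lower, where 637 would be expected by chance, and voom on the recovered counts also called 0. On the deposited mixed values the same test called 2312 genes, 1221 higher and 1091 lower. In 100 simulated data sets of unchanged groups and independent genes the mix alone gave a mean of 584 called genes and a highest count of 852, against a mean of 0.08 without it. The genes with the smallest p among those higher were Tuba4a, Dbh, Actc1, Tuba1b and Col3a1, and among those lower Slc15a2, Timp4, Atg13, Cdo1 and Lgr6. Tuba4a, an alpha-tubulin, was at 767 and 816 CPM against 184 CPM (log2 fold change 2.11, standard error 0.17; limma, adjusted p = 0.208). Dbh, the enzyme that makes noradrenaline, had 93 and 64 counts against 1. Slc15a2, a peptide transporter, had 2 and 1 counts against 171, and Lgr6 74 and 40 counts against 485 (log2 fold change -3.19, standard error 0.41; limma, adjusted p = 0.289). Leaving out 1 library changed the count of calls. It was 3 without Tet2 vector replicate 1, 2 without replicate 2, 87 without oridonin replicate 1 and 107 without oridonin replicate 2.

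The second comparison asked what oridonin changed in the Tet2 hearts. Matrix genes were lower with oridonin by a median log2 of 0.74 over 44 members, 40 of them lower, and stood near the levels of the WT library. Here and for the other lists, this comparison and that with WT share the 2 Tet2 vector libraries with opposite sign. A rise over WT and a fall with oridonin are thus not independent. Fmod was at 0.205 and 0.618 CPM in the oridonin hearts against 12.6 and 11 CPM under vector. Comp, a cartilage and tendon matrix protein, was at 3.28 and 1.58 CPM against 20 and 45.3 CPM, and Postn at 30.6 and 29.3 CPM against 87.0 and 141 CPM. The collagen genes Col3a1 and Col1a2 were at 75.2 and 89.8 CPM against 180 and 163 CPM, and at 78.1 and 76.8 CPM against 163 and 154 CPM. In this list 0 members passed over all genes and 20 passed when adjusted over the list alone, all lower (camera, adjusted p = 2.29e-29, and adjusted p = 0.172 with an estimated correlation).

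**Figure D1:**
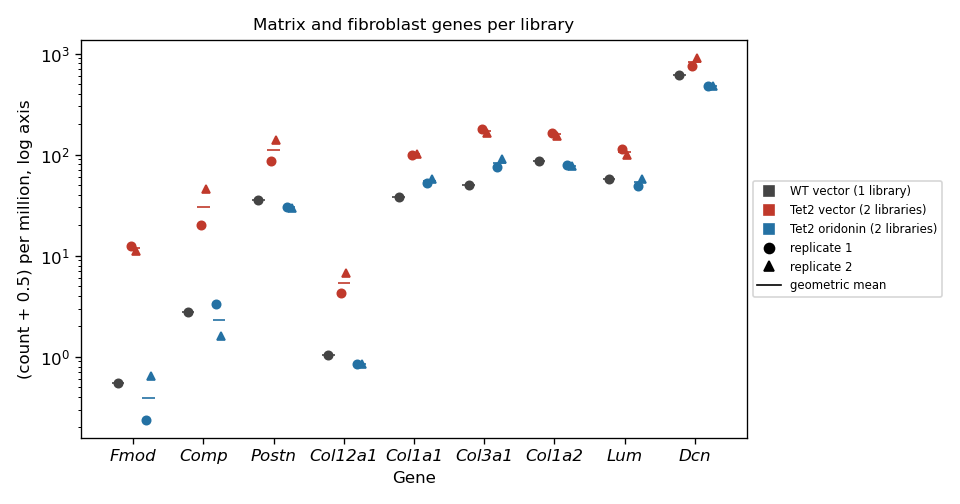
CPM with 0.5 added to each count, on a log axis, for 9 matrix and fibroblast genes in each of the 5 libraries, with circles for replicate 1, triangles for replicate 2 and a bar at the geometric mean of each group. Postn lies at 87.0 and 141 CPM in the Tet2 vector hearts, 30.6 and 29.3 CPM in the oridonin hearts and 35.8 CPM in the WT heart.

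Resident fibroblast markers fell with oridonin by a median log2 of 0.67, with 18 of 18 members lower (camera, adjusted p = 1.07e-19, and adjusted p = 0.172 with an estimated correlation). Lum was at 48.9 and 57.5 CPM against 114 and 99.2 CPM, and Dcn, an abundant fibroblast proteoglycan, at 472 and 482 CPM against 758 and 901 CPM. Here 0 members passed over all genes and 11 passed when adjusted over the list alone. Interferon-stimulated genes fell by a median log2 of 0.29 over 34 members, 32 of them lower (camera, adjusted p = 1.19e-05, and adjusted p = 0.697 with an estimated correlation), with Gbp2 at 25.8 and 28.1 CPM against 43.1 and 52.2 CPM, 0 members past the threshold over all genes and 0 adjusted over the list alone. That call was lost without Tet2 vector replicate 2, at an adjusted p = 0.85. Macrophage and monocyte markers were not called with oridonin (median log2 -0.17 over 25 members; camera, adjusted p = 0.225).

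Genes of the senescence-associated secretory phenotype did not pass as a list with oridonin. Their median log2 fold change was -0.26 over 29 members, 20 of them lower (camera, adjusted p = 0.214, and adjusted p = 0.697 with an estimated correlation), with 0 members past the threshold over all genes and 0 adjusted over the list alone. At an unadjusted p under 0.05 there were 5 lower and 1 higher. Mmp2, a matrix-degrading protease, was at 49.0 and 43.8 CPM against 68.4 and 95.1 CPM, while Ccl7 had 48 and 74 counts against 42 and 8. The arrest and p53 list did not move (median log2 -0.04 over 22 members; camera, adjusted p = 0.91), nor did the list of writers and erasers of methylation on lysine 4 of histone H3 (median log2 0.05 over 25 members; camera, adjusted p = 0.374).

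Several lists rose with oridonin. Red cell genes rose by a median log2 of 0.86 over 6 members (camera, adjusted p = 8.45e-08, and adjusted p = 0.569 with an estimated correlation), with Hba-a1 at 315 and 251 CPM against 196 and 120 CPM. Genes of antigen presentation by MHC class II rose by a median log2 of 0.73 over 7 members (camera, adjusted p = 4.03e-07, and adjusted p = 0.569 with an estimated correlation), with Cd74 at 177 and 135 CPM against 73.0 and 116 CPM. Fatty acid oxidation genes rose by a median log2 of 0.11 over 40 members (camera, adjusted p = 6.35e-05, and adjusted p = 0.569 with an estimated correlation), a call lost without oridonin replicate 1 at an adjusted p = 0.518. In each of these 3 lists 0 members passed over all genes and 0 when adjusted over the list alone. Endothelial markers rose by a median log2 of 0.17 (camera, adjusted p = 0.00116, and adjusted p = 0.569 with an estimated correlation) and cardiomyocyte genes by 0.10 (camera, adjusted p = 0.00822, and adjusted p = 0.569 with an estimated correlation), both with 0 members over all genes and 0 adjusted over the list alone. Without Tet2 vector replicate 1 these 2 calls were lost, at adjusted p values of 0.811 and 0.522, and the endothelial median was -0.05. The endothelial call was also lost without oridonin replicate 1, at 0.0829, and the cardiomyocyte call without oridonin replicate 2, at 0.0698.

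Markers of the atrial chambers stood apart in 1 library. Tet2 vector replicate 1 held 4198 counts of Myl4, 2739 of Myl7, 1034 of Sln and 2899 of Bmp10, where the other 4 libraries had at most 24, 1, 1 and 5. Nppa, the atrial natriuretic peptide, was at 281 and 68.3 CPM under vector, 12.3 and 16.3 CPM with oridonin and 42.5 CPM in WT, and Dkk3 at 107 and 21.7 CPM, 3.49 and 2.81 CPM and 5.30 CPM. Both passed when adjusted over the list alone and 0 members passed over all genes. The atrial list fell with oridonin by a median log2 of 0.47 over 7 members (camera, adjusted p = 0.00427, and adjusted p = 0.697 with an estimated correlation), a call lost without Tet2 vector replicate 1 at an adjusted p = 0.197. The matrix list was higher than in WT in both Tet2 vector libraries, by a median log2 of 0.71 in replicate 1 and 0.83 in replicate 2, and stood at -0.14 and 0.01 in the oridonin libraries. Markers of nerve and glia fell with oridonin by a median log2 of 0.42 over 9 members (camera, adjusted p = 0.0326, and adjusted p = 0.815 with an estimated correlation), with 0 members past the threshold over all genes and 0 adjusted over the list alone. That call was lost without Tet2 vector replicate 1 (adjusted p = 0.645) and without oridonin replicate 2 (adjusted p = 0.618).

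**Figure D2:**
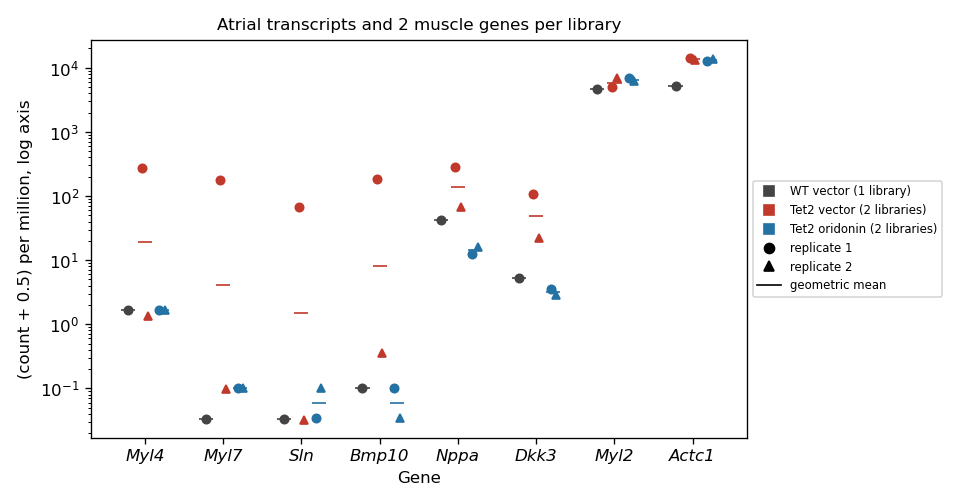
CPM with 0.5 added to each count, on a log axis, for 6 atrial markers and 2 heart muscle genes in each of the 5 libraries, with circles for replicate 1, triangles for replicate 2 and a bar at the geometric mean of each group. Myl4 lies at 270 CPM in Tet2 vector replicate 1 and at 1.30 CPM in replicate 2.

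Gene by gene, limma called 0 of 12734 genes between oridonin and vector in the Tet2 hearts, with a smallest adjusted p of 0.242. At an unadjusted p under 0.05 there were 331 genes, 85 higher and 246 lower, fewer than the 637 expected by chance, and voom called 0. Splitting the same 4 libraries the crossed way, with vector replicate 1 and oridonin replicate 2 against the other 2, called 101 genes, with 2657 at an unadjusted p under 0.05, so that split separated them more strongly than treatment did. The fat cell genes Car3 and Cfd, picked after their values were seen, had 194 and 44 and 76 and 36 counts in the first 2 of these libraries, 5 and 4 and 0 and 1 in the other 2, and 5 and 11 in the WT library. At counts too low to be tested, Plin1 (24 and 9 counts against 0 and 0), Cidec (19 and 13 against 3 and 0) and Adipoq (17 and 3 against 0 and 1) went the same way. Lipe ran the other way, at 28.5 and 36.8 CPM against 40 and 49.8 CPM, as did Cidea, Thrsp and Adig. No test of this split was made for the list. The fat cell list was not called between oridonin and vector (median log2 -0.18 over 8 members; camera, adjusted p = 0.978). On the deposited mixed values 76 genes were called, 7 higher and 69 lower, where simulated unchanged groups of independent genes with the mix gave a mean of 576 and a lowest count of 205. The smallest p among the higher genes belonged to Slc15a2, Lgr6, Timp4, Mybpc2 and Vwa3a, and among the lower genes to Wdfy1, Angptl7, Fmod, Comp and Postn. Slc15a2 had 147 and 90 counts with oridonin against 2 and 1, and Lgr6 570 and 461 counts against 74 and 40 (log2 fold change 3.30, standard error 0.33; limma, adjusted p = 0.345). Timp4, an inhibitor of matrix metalloproteinases with high expression in heart, was at 59.7 and 54.3 CPM against 18.9 and 24.3 CPM. Wdfy1 was at 4.99 and 6.04 CPM against 24.7 and 24.2 CPM (log2 fold change -2.15, standard error 0.23; limma, adjusted p = 0.345). The count of calls was 5 without Tet2 vector replicate 1, 3 without replicate 2, 13 without oridonin replicate 1 and 32 without oridonin replicate 2.

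The third comparison set the oridonin hearts against the WT heart. Matrix genes did not differ as a list (median log2 -0.08 over 44 members; camera, adjusted p = 0.92), with 0 members past the threshold over all genes and 1 adjusted over the list alone. Fibroblast markers were below the WT library, having fallen by a median log2 of 0.29 (camera, adjusted p = 0.00193, and adjusted p = 0.631 with an estimated correlation), with 0 members over all genes and 2 adjusted over the list alone. Interferon-stimulated genes remained above WT by a median log2 of 0.45 (camera, adjusted p = 6.29e-07, and adjusted p = 0.631 with an estimated correlation), with 0 members over all genes and 0 adjusted over the list alone. The secretory list was above WT by 0.26 (camera, adjusted p = 0.0128, and adjusted p = 0.631 with an estimated correlation), with 0 members over all genes and 1 adjusted over the list alone. Tuba4a was at 894 and 906 CPM, Actc1 at 12800 and 13500 CPM and Tuba1b at 118 and 114 CPM in the oridonin hearts, so these 3 kept the levels of the vector hearts and not those of WT. Cdo1, a cysteine-degrading enzyme, was at 2.05 and 2.68 CPM against 31.7 CPM, and Fkbp5, a glucocorticoid-induced chaperone, at 25.1 and 25.2 CPM against 77.2 CPM. Ccn2, the gene of connective tissue growth factor, was at 35.7 and 25.2 CPM against 151 CPM. Under vector it was at 57.5 and 92.6 CPM, so it was below WT in both Tet2 groups. Limma called 0 genes in this comparison (smallest adjusted p 0.126), with 791 at an unadjusted p under 0.05, 342 higher and 449 lower. Voom called 0, and the deposited mixed values gave 996, 428 higher and 568 lower. The count was 10 without oridonin replicate 1 and 24 without oridonin replicate 2.

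The last comparison asked whether oridonin moved genes against their change in Tet2 vector hearts. As 0 genes were called, the 1221 genes at an unadjusted p under 0.05 between Tet2 vector and WT were taken. Of these, 84.5% had the opposite sign with oridonin, where simulated unchanged groups gave a mean of 80.5% and a highest value of 84.8%, because both comparisons use the Tet2 vector libraries with opposite sign. At the same p threshold the share lay inside the simulated range, but the simulated lists held a mean of 640 genes. With each simulated list cut to the observed length, the simulated mean was 78.9% and the highest value 81.1%, and the observed share lay above it. The simulated genes were independent of each other, while real genes vary together, with an estimated correlation of 0.875 in the red cell list. The simulated ranges may thus be too narrow, here and for the values below, and a value outside them settles nothing. The correlation of the fold changes across genes, which are not independent replicates, was -0.515 against a simulated mean of -0.406 and a lowest simulated value of -0.468. The covariance was -0.117 against a mean of -0.095, inside the simulated values from -0.119 to -0.0826. Among genes higher in Tet2 vector hearts and lower with oridonin at an unadjusted p under 0.05, 94 were shared, where independent lists would share 12.4. In the other direction 46 were shared, where independent lists would share 3.9. Simulated unchanged groups, which share the vector libraries, gave 72 to 100 in the first direction and 27 to 50 in the other with lists cut to the observed lengths, so both counts lay inside these ranges. At the same p threshold, where the simulated lists had other lengths, they gave 49 to 86 and 52 to 95. The first count lay above that range and the other below it. The 2 vector libraries could not be split with at least 2 in each part. Igtp, Gbp2 and Col3a1 were among the genes that went up and then down, and Slc15a2, Lgr6 and Timp4 among those that went down and then up.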

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

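The deposited values, the voom fit, a pseudocount of 1 CPM, median-of-ratios factors for the gene counts, the other scalings for the lists and the crossed pairing were chosen after the data were seen. Of the settings that left 5 libraries and the threshold in place, the ones without a mix or a block called 0 genes in all 3 comparisons, as reported, and so did an FDR of 0.1. The deposited mixed values called 2312 genes in Tet2 vector against WT, 76 in oridonin against vector and 996 in oridonin against WT, a change that follows from a replicate spread 0.5 times as large. Unadjusted p under 0.05 with a log2 fold change of at least 1 gave 572, 117 and 329. The deviations of replicates with the same number correlated at -0.296 across genes. This gave no sign that the numbers pair the libraries, but 1 difference per group cannot exclude it. A replicate block gave 10, 9 and 6 calls, and the crossed pairing 432, 44 and 184. Leaving out 1 library gave 2 to 107 calls in Tet2 vector against WT, 0 to 32 in oridonin against vector and 0 to 24 in oridonin against WT, and using only the groups compared gave 103 in the first and 1 in the last. In Tet2 vector against WT, leaving out oridonin libraries keeps every fold change, so only the estimate of spread differed there. The same holds for the list calls of that comparison. The cause of the other changes was not tested.

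The share of genes with the opposite sign was 78.2% on the deposited values, 81.8% under the crossed pairing, 85.3% with a replicate block, and 79.1% to 92.1% with 1 library left out. Called lists numbered 14, 10 and 12 in the 3 comparisons. They fell to 0, 0 and 0 with an estimated correlation and to 1, 0 and 1 with fry, and were 17, 10 and 13 with the replicate block. Fry also rests on 2 residual degrees of freedom, and its test for changes in either direction called 9, 1 and 7 lists. The 9 included the nerve and glia list (fry, adjusted p = 0.00511), which camera did not call there. Camera with an estimated correlation has only 2 residual degrees of freedom, so its fall in calls cannot be put down to correlation among members alone. Correlation may add to it in lists such as red cell genes (estimated at 0.875) and nuclear respiratory chain genes (0.723). With 1 library left out there were 14 to 17, 11 to 16 and 12 to 14. The list of nuclear respiratory chain genes turned its direction, with no call, in Tet2 vector against WT under the crossed pairing (adjusted p = 0.437) and without Tet2 vector replicate 2 (0.255), and in oridonin against WT under the crossed pairing (0.866) and without oridonin replicate 1 (0.744). With 1 library left out its adjusted p ran from 5.5e-07 to 0.255 in the first and from 3.99e-07 to 0.744 in the last. The cause was not tested. Of 297 gene and comparison pairs, 267 kept the sign of their fold change in every alternative, as did all 30 with the smallest p. Those 30 were picked in the same data for groups that do not overlap. Many alternatives also leave the group means nearly unchanged, so the kept sign is no independent check. Libraries held 14574823 to 15535778 counts, and the effect of depth was not tested.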

Other observations

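The tests in this part were all chosen after the results were seen, apart from the list tests. Genes induced by glucocorticoids were lower in all 4 Tet2 libraries than in the WT library and fell in Tet2 vector against WT by a median log2 of 0.43 over 18 members (camera, adjusted p = 4.21e-05, and adjusted p = 0.503 with an estimated correlation; fry, adjusted p = 0.021). Fkbp5 was at 26.8 and 21.8 CPM against 77.2 CPM, Zbtb16 at 16.0 and 7.56 CPM against 122 CPM and Klf15 at 50.7 and 42.7 CPM against 98.9 CPM, with 0 members past the threshold over all genes and 5 adjusted over the list alone. The same list fell by 0.78 in oridonin against WT (camera, adjusted p = 6.29e-07, and adjusted p = 0.631 with an estimated correlation; fry, adjusted p = 0.00474), with 0 members over all genes and 7 adjusted over the list alone. Antioxidant genes driven by NRF2 fell by a median log2 of 0.24 in Tet2 vector against WT (camera, adjusted p = 0.00178, and adjusted p = 0.503 with an estimated correlation), a call lost without Tet2 vector replicate 1 at 0.203. Gclm was at 19.1 and 18.5 CPM against 62.7 CPM, and was the 1 member that passed adjusted over the list alone, with 0 over all genes. With a single WT heart, a difference of that animal and a difference of genotype cannot be separated in any of these values.

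Further lists moved in Tet2 vector against WT. Red cell genes fell by a median log2 of 0.99 over 6 members (camera, adjusted p = 0.00184, and adjusted p = 0.683 with an estimated correlation), endothelial markers by 0.34 (0.014, and adjusted p = 0.503 with an estimated correlation) and the histone H3 lysine 4 methylation list by 0.38 (0.0158, and adjusted p = 0.873 with an estimated correlation). The red cell median log2 over WT was -0.60 in Tet2 vector replicate 1 and -1.38 in replicate 2. Genes of the mitochondrial genome rose by 0.43 (0.00184, and adjusted p = 0.503 with an estimated correlation), cell division genes by 0.39 (0.0145, and adjusted p = 0.811 with an estimated correlation), fibroblast markers by 0.45 (0.015, and adjusted p = 0.503 with an estimated correlation) and nuclear respiratory chain genes by 0.12 (0.0388, and adjusted p = 0.873 with an estimated correlation). In these lists 0 members passed over all genes and 0 adjusted over the list alone. Leaving out Tet2 vector replicate 1 ended the endothelial (0.308) and cell division (0.0561) calls, leaving out replicate 2 ended the methylation call (0.175), and leaving out either oridonin library ended the fibroblast call (0.0526 and 0.0537) and the respiratory chain call (0.0985 and 0.0914). In oridonin against WT the calls were macrophage and monocyte markers (median log2 0.47), genes of the mitochondrial genome (0.41), cell division genes (0.61), MHC class II genes (0.80) and nuclear respiratory chain genes (0.12), all higher, and NRF2 targets (-0.33), heat shock genes (-0.30) and the histone methylation list (-0.31), all lower. With an estimated correlation the adjusted p of these 8 lists lay between 0.631 and 0.932. In each, 0 members passed over all genes, and 1 passed adjusted over the list alone in the macrophage, NRF2 and heat shock lists and 0 in the others. Without oridonin replicate 1 the heat shock (0.0933) and methylation (0.134) calls were lost. Besides the arrest and p53 list, the lists called in neither main comparison were inflammasome and NF-kB genes, B cell, smooth muscle and fat cell markers, load-responsive genes, ion channels, glycolysis, stress response, heat shock, immediate early and clock genes and DNA methylation enzymes. Their medians lay between -0.41 and 0.20 in Tet2 vector against WT and between -0.18 and 0.30 in oridonin against vector. Single members of these that passed adjusted over the list alone, with 0 over all genes, were Dbp, Herpud1 and Vldlr in the first comparison and Hspa1a and Nppa in the other. Clock genes peak at different hours, so a list test of 1 direction cannot exclude a time-of-day difference. Dbp was at 37.0 CPM in WT against 85.5 and 98.9 CPM under vector, and Bmal1 at 7.55 against 1.29 and 3.72 CPM. Of the 20 clock genes, 7 were higher and 13 lower in that comparison. In Tet2 vector against WT the nerve and glia (median log2 0.29, camera adjusted p = 0.131), atrial (0.39, 0.458) and MHC class II (0.12, 0.827) lists were not called either, with 0 members over all genes in each and 2 (Dbh and Tubb3, higher), 2 (Dkk3, higher, and Clu, lower) and 0 adjusted over the list alone. In oridonin against vector neither were glucocorticoid (0.04, 0.89), NRF2 (-0.03, 0.747), cell division (0.12, 0.105), nuclear respiratory chain (-0.02, 0.374) and mitochondrial genome genes (0.02, 0.433). Markers of neutrophils, T and NK cells, skeletal muscle, epicardium, lung and sex had fewer than 5 tested members and were not tested.

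Atrial transcripts marked 1 of the 5 libraries. Myl4, Myl7, Sln and Bmp10 summed to 700 CPM in Tet2 vector replicate 1, and the highest other library reached 0.255% of that. The Tet2 transplant as the source is argued against by Tet2 vector replicate 2, whose sum was 1.01 times that of WT. A candidate explanation is atrial tissue in the piece of heart that gave that 1 library. Whether the lower Nppa and Dkk3 with oridonin rests on it stays open, since replicate 2, the vector library without these atrial transcripts, was still at 68.3 CPM of Nppa against 12.3 and 16.3 CPM. Replicate 2 stood apart in its own way, with Nppb at 418 CPM against 55.5 CPM in replicate 1, 103 CPM in WT and 76.1 and 135 CPM with oridonin. Myh7 was at 320 CPM there against 128 CPM in replicate 1. The load-responsive list, which holds Nppa, had a median log2 over WT of 0.55 in replicate 2 and -0.10 in replicate 1. Neither vector library is thus a plain reference for Nppa.

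Matrix genes were high in both vector hearts and low in both oridonin hearts. Atrial tissue is argued against, since over the 44 genes replicate 1 minus replicate 2 had a median log2 of -0.162 (quartiles -0.575 and 0.172). A lower share of heart muscle RNA under vector would have raised endothelial markers too, but those had a median log2 fold change of 0.175 with oridonin (quartiles 0.054 and 0.279), and this argument is weak, since without Tet2 vector replicate 1, the library with atrial transcripts, that median was -0.05 (adjusted p = 0.811). Fibroblast markers outside the matrix list moved with it, at a median of -0.665 with 18 of 18 lower. Fewer fibroblasts in the oridonin hearts may account for part of the pattern, as may lower expression per fibroblast, which was not tested. Some of these markers, such as the proteoglycan gene Dcn, belong to the matrix themselves, so they cannot tell these explanations apart. An effect of oridonin and a difference between 2 pairs of animals both stay open.

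Genes with an unadjusted p under 0.05 for oridonin against vector lay close together on 2 chromosomes. Of 428 windows of 10 Mb, the densest was on chromosome 11 from 40 to 50 Mb, with 8 of 44 genes where 1.16 were expected, and chance placement gave as dense a window with a permutation p of 0.003 (10000 permutations, one-sided), although tandem copies such as Tgtp1 and Tgtp2 count 2 times there. On chromosome 1 from 130 to 140 Mb there were 9 of 75 genes where 1.97 were expected (permutation p = 0.0261), among them Fmod, Lgr6, Rab7b, Klhl12 and Ddx59. A candidate explanation is a chromosome segment of another mouse strain that differs between these hearts, and the WT value lay nearer to the oridonin mean in 8 of these 9 genes, against 67.4% of all such genes. As the genes were picked for the pattern and no genotype was measured, this and co-regulation of neighbours cannot be told apart.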
